A study of Caenorhabditis elegans with 8 samples.

How the data were processed

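RNA of whole Caenorhabditis elegans was sequenced in 8 libraries from a single strain, 4 of worms given ethanol and 4 of worms given 5-Ph-IAA. The labels describe the strain as carrying an auxin-inducible degron (AID) for DAF-15 in neurons. In this system a plant F-box protein binds a short tag on the target protein once auxin is present and sends the target to the proteasome. 5-Ph-IAA (5-phenyl-indole-3-acetic acid) is an auxin analog used as the trigger, and ethanol is the control treatment. DAF-15 is the worm Raptor, a subunit of the TORC1 kinase complex. Per the labels' protocols, worms fed on E. coli OP50 received either treatment from the L4 stage for 24 h and were collected on day 1 of adulthood. Total RNA was taken up in TRIzol and purified on columns, and 3 ug of it entered each library, made with a VAHTS Universal V8 kit. The dose of 5-Ph-IAA and whether the kit was run with strand marking are not given in the sources used here.

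The deposited values are whole-number counts of reads per gene, 1 file per library. Per the submitters' processing notes, FastQC 0.11.5, TopHat2 (a spliced aligner), HTSeq (a read counter) and DESeq2 were used, with no role stated for any of them. The genome build, the annotation release and the strand setting behind the counts are not given in the sources used here. Each file lists 46739 genes by WormBase identifier and closes with 5 summary lines of the kind HTSeq writes, which name no gene and were left out of library sizes and tests. Of the counts in each file, between 47.74% and 48.06% stood in the line for reads overlapping no gene, between 4.14% and 4.55% in the line for reads with more than 1 alignment and between 0.296% and 0.390% in the line for reads overlapping several genes. By HTSeq's default, reads with more than 1 alignment count for no gene. Of 7 sets of protein-coding genes that share a symbol and a length and hold at least 100 counts, 0 had a lowest copy with 90% of the counts of the highest, as counting such reads at every copy would give. Genes with near-identical copies are therefore measured only through the reads that tell the copies apart. Of the identifiers, 46484 were found in Ensembl release 115 (assembly WBcel235), which supplied symbols and coordinates, and 43720 had a symbol there. Coordinates given here are 1-based positions of that annotation, not of the one used for counting.

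Between 7354710 and 10893322 reads fell in genes per library. Genes passing edgeR's filterByExpr entered the test, which left 12021 genes. Libraries were scaled with TMM factors (0.986 to 1.02), and the groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p given for a single gene comes from this test unless another is named. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over the 4 libraries of a group, and log2 fold changes are 5-Ph-IAA over ethanol with their standard error (SE). The SE was derived as the absolute log2 fold change divided by the square root of the F statistic of the test. It therefore need not match the adjusted p of every gene. The common biological coefficient of variation was 7.67%. Spearman correlations over tested genes lay between 0.9901 and 0.9922 within groups and between 0.9894 and 0.9925 across them. None of the 12 pairs of replicates had counts as close as sampling noise (chi-square per degree of freedom 2.53 to 9.10), so every library was counted once. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

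The labels number the libraries 1 to 4 in both groups without saying what a number marks. Deviations from the group means (log2 CPM, prior count 2) correlated between libraries of the same number at 0.1474, 0.1305, 0.1002 and 0.1441, against -0.099 to 0.0103 between libraries of different numbers. Each of the 8 libraries correlated best with the one of its own number, and of the 24 ways to pair the groups 1, the labelled one, gave as large a sum. The bar set for pairing was a correlation above 0.1 in every pair, which was met with a narrow margin (with a prior count of 0.5 the lowest correlation was 0.0957). The numbers were therefore treated as pairing the libraries. The comparison was made without a block, and again with the replicate number as a block, whose value is given beside a result where it changed a call or moved a count by more than 1.5 times.

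For gene groups, 56 lists of symbols were fixed before the data were examined, covering TOR signalling, translation, protein turnover, stress, xenobiotic metabolism, immunity, reproduction, cuticle, neurons, other tissues, metabolism and signalling. Each was tested with limma's camera (limma 3.58.1, preset correlation 0.01 between genes, log2 CPM, at least 5 tested members), adjusted over the lists. The same test with an estimated correlation, and fry, a rotation test of a list's own genes, were the alternatives. Camera asks whether a list moved differently from the other genes, whereas fry asks whether its own genes moved. Fry mixed asks the same without regard to direction. The mitochondrially encoded list was matched by chromosome, since the annotation names those genes differently. Gene classes, the letters before the dash of a symbol, were scanned in the same way where at least 10 members were tested, which gave 114 classes.

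Genes were named by a rule set in advance. It took daf-15, up to 12 genes in each direction with the largest fold change among those past 0.05 with a mean log2 CPM of at least 1 and groups that did not overlap, up to 4 members with the smallest unadjusted p from each list past the threshold and from 8 core lists, and up to 2 from each class past the threshold. Any further gene is said to have been chosen after its values were seen. Alternatives were RLE and upper quartile factors, no filter and a stricter filter (at least 50 counts in 4 libraries), DESeq2 1.42.0, limma-voom, thresholds of 0.01 and of at least 2-fold, the replicate block and each library left out in turn. Thinning all libraries to the total of the smallest one was added later.

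The scripts were tested on simulated counts for the 12021 genes of this comparison, with 50 genes changed at each of 4 fold sizes. Without the block the test recovered 12% of genes changed 1.25-fold, 60% at 1.5-fold, 80% at 2-fold and 98% at 3-fold. With the block it recovered 26%, 62%, 82% and 98%. Of its calls in a single run, 6% were false without the block (8 calls) and 12.4% with it (19 calls). The blocked rate lay above the nominal 0.05, and 8 calls are too few to tell the other from it. Libraries of the same number were given a shared effect with a log2 SD of 0.05, added to a spread estimated without the block. The blocked rates therefore need not hold for the blocked fit of these data. A list of 30 genes shifted by 0.3 on the log2 scale had an adjusted p of 4.07e-35 by camera with the preset correlation and 0.000352 with an estimated one, and 0 of 50 unshifted lists passed. All lists held random genes simulated independently of each other. The simulation therefore cannot show how often camera with the preset correlation passes families whose genes vary together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.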

Results

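Gene expression in whole adult worms was compared between 4 libraries of worms given 5-Ph-IAA, the trigger for degradation of DAF-15 in neurons, and 4 libraries of worms of the same strain given ethanol. The reads counted in genes numbered 7354710, 8546426, 7933885 and 10893322 in ethanol replicates 1 to 4, and 9709094, 7847233, 7745664 and 9179212 in 5-Ph-IAA replicates 1 to 4. The comparison asks which transcripts of the whole animal differ after 24 h of treatment aimed at the TORC1 subunit DAF-15 in neurons. No library came from worms without the degron, so the compound and the loss of DAF-15 were applied together.

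The transcript of daf-15 itself (WBGene00000911, chromosome IV: 9386208 to 9394979, plus strand) stood at 121.1 ± 6.89 CPM with ethanol and 119.1 ± 6.20 CPM with 5-Ph-IAA (SD, n = 4 each). Its log2 fold change of -0.022 (SE 0.057, edgeR adjusted p = 0.999) was smaller than the spread between replicates. Degradation acts on the protein, so this transcript does not check the treatment, and most reads of the gene in whole-worm RNA can come from tissues other than neurons.

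Without the replicate block few transcripts passed the threshold, and those that did were mostly genes of low abundance. Of 12021 tested genes, 10 rose and 2 fell with 5-Ph-IAA at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The genes that rose held 2 antimicrobial peptide genes of the nlp-29 cluster (nlp-29 and nlp-34), 2 genes of the fungus-induced protein family (fipr-23 and fip-5), the cytochrome P450 gene cyp-35C1 and 5 genes without a name of their own. Both genes that fell, nspc-9 and nspc-4, belong to a nematode-specific peptide family, group C. With the replicate number as a block, 88 genes passed (57 higher and 31 lower), and these included all 12. The blocked number was 84 with limma-voom, 57 with the stricter filter, 51 without replicate 2 and 24 with DESeq2. Unblocked DESeq2 called 29. Of the 88, 20 differed at least 2-fold and 45 by less than 1.5-fold. The median log2 fold change over all tested genes was -0.0009, and at an unadjusted p under 0.05 there were 530 genes without the block and 831 with it, against 601 by chance.

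**Figure D1:**
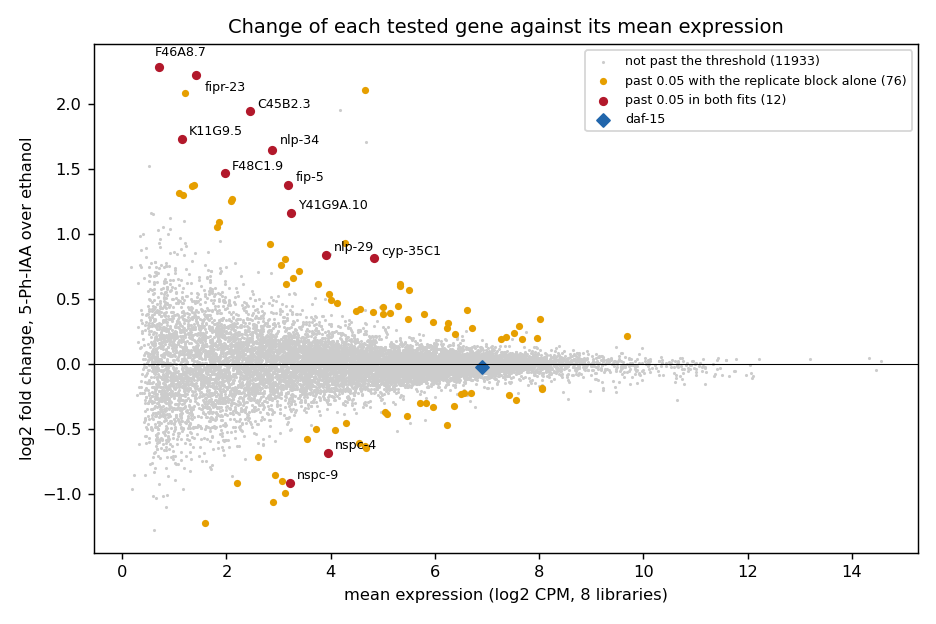
Log2 fold change (5-Ph-IAA over ethanol, vertical axis) of each of the 12021 tested genes against its mean expression in log2 CPM (horizontal axis), in the fit without the block. Red points mark the 12 genes past 0.05 in both fits, orange points the genes past 0.05 with the replicate block alone, and the blue diamond daf-15, which lies at -0.022.

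A pair of peptide genes of the epidermis rose. The transcript of nlp-34 (WBGene00015046, chromosome V: 3978825 to 3979134), an antimicrobial peptide gene of the epidermis, went from 3.48 ± 1.05 CPM with ethanol to 10.7 ± 2.80 CPM with 5-Ph-IAA (SD, n = 4), a 3.14-fold difference (log2 1.65, SE 0.225, edgeR adjusted p = 0.00158). Its neighbour nlp-29 (WBGene00003767, V: 3984425 to 3984847), known as a reporter of fungal infection and wounding of the epidermis, went from 10.75 ± 2.23 to 19.02 ± 2.79 CPM, or 1.79-fold (log2 0.84, SE 0.148, edgeR adjusted p = 0.0130). It did not pass without ethanol replicate 4 or 5-Ph-IAA replicate 1, 2 or 4 (0.0733, 0.0570, 0.0854 and 0.0686). The list of epidermal antimicrobial peptides had 19 tested members, of which these 2 rose, 0 fell, and 17 did not pass. Adjusted over the list alone, 5 members were higher. As a set the list was higher by camera (adjusted p = 0.0114, median log2 fold change 0.10, 12 members above 0 and 7 below), a call that was lost with an estimated correlation (adjusted p = 0.724), with the stricter filter (0.112) and without ethanol replicate 4 (0.278). With the block, cnc-6, a caenacin, also passed (4.40-fold, log2 2.14, SE 0.379, edgeR adjusted p = 0.000566), as did nlp-30 (log2 1.198, SE 0.287, edgeR adjusted p = 0.0394, higher in 3 of 4 pairs), a gene between nlp-34 and nlp-29 that was named after its values were seen. Without the block cnc-6 passed with DESeq2 (0.0194) and with no filter (1.34e-05). The blocked calls ended without replicate 2 for cnc-6 (0.0623), and with DESeq2 or without replicate 1 or 2 for nlp-30 (0.543, 0.490 and 0.230). Of the members that did not pass, cnc-4 had a log2 fold change of 0.461 and fipr-1 of -0.408, both named after their values were seen, and cnc-2, at 1.63-fold, did not pass in either fit (edgeR adjusted p = 0.669 without the block and 0.156 with it).

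The fungus-induced protein genes fip and fipr code for short peptides of the same kind. The transcript of fipr-23 (WBGene00007990, I: 14153228 to 14154195) was scarce with ethanol, at 0.843 ± 0.133 CPM, and reached 3.93 ± 1.06 CPM with 5-Ph-IAA (4.67-fold, log2 2.23, SE 0.317, edgeR adjusted p = 0.00158). That of fip-5 (WBGene00009620, X: 10302741 to 10303143) went from 5.02 ± 1.27 to 12.9 ± 3.53 CPM (2.60-fold, log2 1.38, SE 0.207, edgeR adjusted p = 0.00281). Of the 12 tested genes of the family, named as a family after the values were seen, 2 rose, and the log2 fold changes of all 12 lay between -0.44 and 2.23 with 8 above 0. The nearest neighbours of fipr-23 on chromosome I, fipr-22 and fipr-24, had log2 fold changes of 0.37 (SE 0.142) and 0.46 (SE 0.179) and did not pass (edgeR adjusted p = 0.999 for each). With the block fip-6, named after its values were seen as were these neighbours, was also higher (log2 0.62, SE 0.13, edgeR adjusted p = 0.00555), though not with DESeq2 (0.207).

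Among genes of xenobiotic metabolism 1 rose without the block. The transcript of cyp-35C1 (WBGene00007362, V: 13896663 to 13898487), which codes for a cytochrome P450 of the xenobiotic-inducible CYP-35 family, went from 20.3 ± 4.02 to 35.9 ± 4.03 CPM (SD, n = 4), or 1.76-fold (log2 0.82, SE 0.122, edgeR adjusted p = 0.00275), and was higher in 4 of 4 numbered pairs. With the block cyp-35A2 (1.495-fold, edgeR adjusted p = 9.22e-07), cyp-35A3 (1.78-fold, 0.00568, and 0.00300 without the block and filter) and cyp-35A5 (2.63-fold, 0.0358) also rose, while cyp-35B1, at 1.33 CPM with ethanol and 1.38 CPM with 5-Ph-IAA, did not pass (edgeR adjusted p = 0.993). The genes cyp-35A2 and cyp-35B1, and the family as a group, were named after their values were seen. The blocked calls ended with DESeq2 or without replicate 4 for cyp-35A3 (0.262 and 0.0907), and with DESeq2 or without replicate 1, 2 or 3 for cyp-35A5 (0.513, 0.154, 0.137 and 0.210). All 5 tested cyp-35 genes had a log2 fold change above 0, with a median of 0.81. These genes are close paralogs, so their separate values are uncertain. The list of cytochrome P450 enzymes, with 42 tested members, was higher by camera (adjusted p = 0.0442, median log2 fold change 0.058) with 1 member past the threshold, 2 when adjusted over the list alone and 4 with the block. Another member, cyp-34A9, stood at 1.601-fold and did not pass in either fit (edgeR adjusted p = 0.999 without the block and 0.486 with it). The call was lost with an estimated correlation (adjusted p = 0.724), with either other filter, and without ethanol replicate 1 or 4 or 5-Ph-IAA replicate 1 or 4 (0.0706 to 0.174).

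The UDP-glucuronosyltransferases, enzymes that attach glucuronic acid or glucose to foreign compounds, were also higher as a list (50 tested members, adjusted p = 0.00979 by camera, median log2 fold change 0.097), and again the call was lost with an estimated correlation (adjusted p = 0.724), and without ethanol replicate 1 or 4 (0.0539 and 0.115). None of their members passed in edgeR with the filter used, DESeq2 or limma-voom without the block (ugt-13 did in edgeR with no filter, 0.00580), with 8 at an unadjusted p under 0.05 in edgeR and 0 when adjusted over the list alone. Adjusted over the list alone with the block, 8 members were higher and 1 was lower. With the block ugt-13 rose (1.36-fold, edgeR adjusted p = 0.00188) and ugt-4 fell (0.699-fold, 0.0436), and ugt-22, named after its values were seen, rose 1.35-fold (9.22e-07). The calls ended with blocked DESeq2 for ugt-13 (0.0744) and ugt-4 (0.745), and for ugt-4 also with limma-voom, with the stricter filter and without replicate 1, 2 or 4 (0.0563 to 0.338). For comparison ugt-5 and ugt-16 stood at 1.45-fold and 1.63-fold without passing in either fit (edgeR adjusted p with the block 0.139 and 0.0723). The glutathione S-transferase list did not pass by camera (35 tested members, adjusted p = 0.562), though with the block gst-5 was higher (1.39-fold, edgeR adjusted p = 0.0253) and gst-38 lower (0.757-fold, 0.000948), both named after their values were seen. Fry mixed passed this list with the block (adjusted p = 0.0142) and not without it (0.440). The call of gst-5 ended with DESeq2 (0.520) and without replicate 2, 3 or 4 (0.125 to 0.196). The lists of short-chain dehydrogenases and of P-glycoprotein and MRP transporters did not pass by camera either (adjusted p = 0.359 and 0.405).

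Of the 10 tested nspc genes, a family of nematode-specific peptides, 2 fell without the block. The transcript of nspc-9 (WBGene00009634, X: 12342946 to 12343379) went from 11.97 ± 2.16 CPM with ethanol to 6.33 ± 1.297 CPM with 5-Ph-IAA (0.530-fold, log2 -0.92, SE 0.178, edgeR adjusted p = 0.0290). That of nspc-4 (WBGene00044339, X: 8537956 to 8538362) went from 18.9 ± 3.03 to 11.8 ± 1.54 CPM (0.623-fold, log2 -0.68, SE 0.137, edgeR adjusted p = 0.0412). Neither passed with limma-voom (0.0775 for each) or the stricter filter (0.0856 for each), nor nspc-4 with upper quartile factors (0.0566) or nspc-9 after thinning to equal depth (0.0787). Leaving out ethanol replicate 1 or 2 or 5-Ph-IAA replicate 1, 2 or 4 ended both calls (0.0686 to 0.166 for nspc-9, 0.131 to 0.215 for nspc-4), and leaving out ethanol replicate 3 that of nspc-9 (0.0703). All 10 tested nspc genes had a log2 fold change below 0, from -0.92 to -0.26 with a median of -0.65, and all 10 lie on the X chromosome. In the open scan of 114 gene classes nspc stood first (camera adjusted p = 5.97e-15), yet with an estimated correlation of its genes it did not pass (adjusted p = 0.564), nor by fry in one direction (0.306), while fry mixed passed it without the block (0.0451) and not with it (0.0530). Fry mixed without the block also passed the classes inx, nlp, ttr and cyp (adjusted p = 0.00277, 0.00277, 0.00338 and 0.0451). With the block nspc-14, nspc-10 and nspc-1 also fell (edgeR adjusted p = 0.00241, 0.0394 and 0.0417), named after their values were seen. With blocked DESeq2 none of the 5 passed (0.0556 for nspc-9, 0.0686 for nspc-4, and 0.0770, 0.755 and 0.833 for these 3). Without replicate 2 the blocked call ended for nspc-4 (0.0674) and for these 3 (0.0761, 0.353 and 0.526). The call also ended with the stricter filter and without replicate 3 for nspc-10 (0.0644 and 0.483), and with limma-voom and without replicate 4 for nspc-1 (0.0580 and 0.234). Members of this family resemble each other, so the value of any single nspc gene is uncertain.

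Of the 5 genes that rose without a name of their own, C45B2.3 (WBGene00016660, X: 6082960 to 6083412) went from 2.18 ± 0.843 to 8.34 ± 3.31 CPM (edgeR adjusted p = 0.0281), and K11G9.5 (WBGene00019655, V: 6685807 to 6688492) from 0.914 ± 0.206 to 3.03 ± 0.275 CPM (0.0190). F48C1.9 (WBGene00018601, I: 5332249 to 5332780) went from 1.94 ± 0.796 to 5.37 ± 1.28 CPM (0.0218). Y41G9A.10 (WBGene00044901, X: 2945803 to 2946558) went from 5.64 ± 1.58 to 12.63 ± 1.47 CPM (0.00275). For C45B2.3, F48C1.9 and K11G9.5 the call ended without ethanol replicate 1 or 4 or 5-Ph-IAA replicate 1 or 4 (0.0511 to 0.160). It also ended without ethanol replicate 2 for C45B2.3 (0.0853), ethanol replicate 3 for F48C1.9 (0.0572) and 5-Ph-IAA replicate 2 for F48C1.9 and K11G9.5 (0.128 and 0.0854), and with limma-voom or after thinning for C45B2.3 (0.175 and 0.0787). With blocked DESeq2 K11G9.5 (0.0995) and F46A8.7 (0.0556) did not pass. F46A8.7 (WBGene00009750, I: 11238117 to 11238227) fell outside the rule for naming because of its low level, was named after its values were seen, and went from 0.473 ± 0.0762 to 2.33 ± 0.270 CPM (0.00677). All 12 genes that changed are annotated as protein-coding, and the values of the 4 libraries of one group did not overlap those of the other group for any of them. The same separation held for 318 of the 12021 tested genes, or 2.65%, where chance gives 2.86%.

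**Figure D2:**
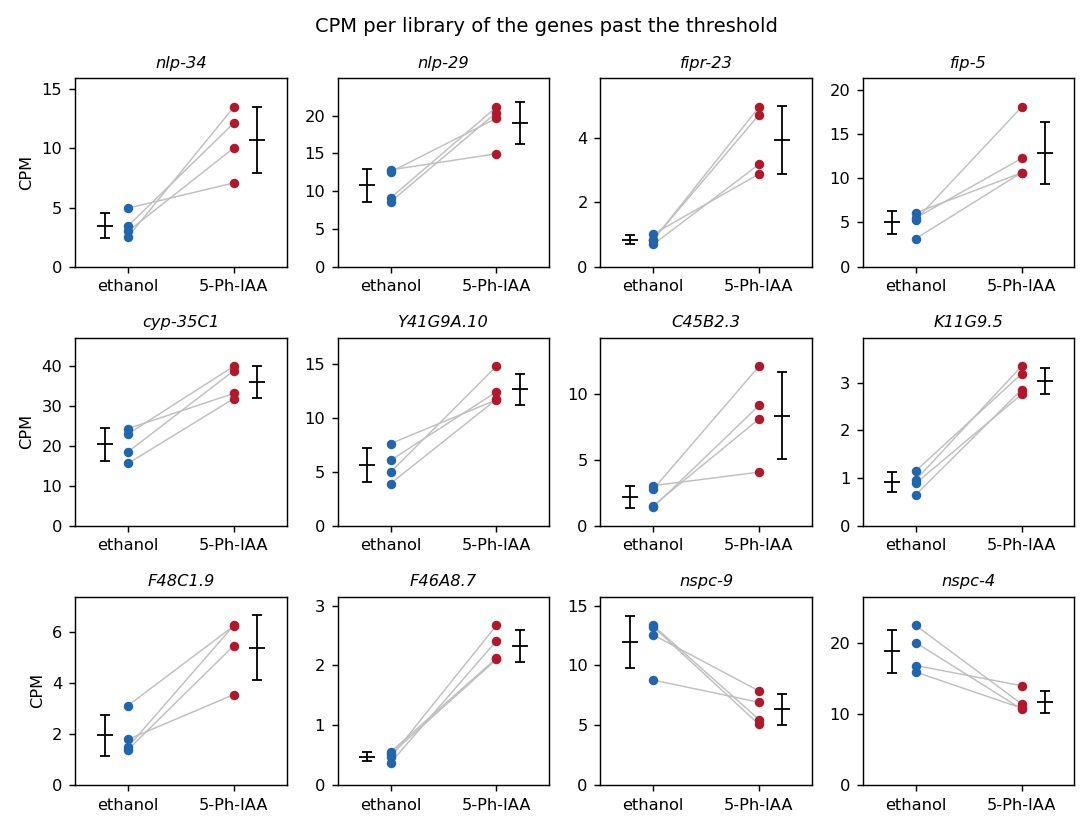
CPM per library (vertical axes, each starting at 0) of the 12 genes past the threshold, with ethanol in blue and 5-Ph-IAA in red, lines joining libraries of the same replicate number, and black bars for the mean ± SD of the 4 libraries. In every panel the 2 groups are apart, with nlp-34 at 2.52 to 4.95 CPM with ethanol and 7.08 to 13.49 CPM with 5-Ph-IAA.

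Of the 20 tested genes of the cytosolic heat shock list, 3 were lower with the block and 0 passed without it (1 at an unadjusted p under 0.05 in edgeR, 0 past in DESeq2 or limma-voom). Levels of hsp-16.1, a small heat shock protein gene, ranged from 2.89 to 19.77 CPM over the ethanol libraries and from 1.62 to 9.65 CPM over the 5-Ph-IAA libraries, and 5-Ph-IAA was lower in 4 of 4 pairs. Without the block its log2 fold change was -0.90 (SE 0.791, edgeR adjusted p = 0.999), and with the block -0.85 (SE 0.176, 0.00468). The Hsp70 genes F44E5.4 (block log2 fold change -0.88, SE 0.182, edgeR adjusted p = 0.00468) and hsp-70 (-0.76, SE 0.182, 0.0241) were also lower with the block, whereas F44E5.5, hsp-16.2 and hsp-16.41 did not pass with it (0.984, 0.885 and 0.882). The calls of hsp-16.1, F44E5.4 and hsp-70 ended with blocked DESeq2 (0.245, 0.318 and 0.867) and without replicate 4 (0.237, 0.495 and 0.373), and that of hsp-70 also without replicate 2 (0.381). These genes were named after their values were seen, and hsp-16.1 and F44E5.4 have near-identical copies. The agreement of the 4 pairs was a condition of choosing hsp-16.1, so it adds no support. The list of the cytosolic heat shock response (20 tested members, 14 below 0, median log2 fold change -0.051) passed with the block (camera adjusted p = 0.00834, and 0.770 with an estimated correlation) and not without it (0.212). Leaving out ethanol replicate 1, 5-Ph-IAA replicate 2 or 5-Ph-IAA replicate 4 brought the unblocked list past the threshold (0.0169, 0.0429 and 0.00771), and without ethanol replicate 4 it stood on the other side of 0 (0.977).

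Among genes of metabolism and longevity pathways, 3 lists were higher by camera and lost the call with an estimated correlation. Lipid breakdown and the fasting response (36 tested members) had an adjusted p of 0.0151 (adjusted p = 0.629 with an estimated correlation) and a median log2 fold change of 0.065. The genes reported as raised by the transcription factor DAF-16 (24 tested members) had an adjusted p of 0.0101 (adjusted p = 0.724 with an estimated correlation) and a median of 0.065. Glycolysis, gluconeogenesis and trehalose (29 tested members) had 0.00979 (adjusted p = 0.724 with an estimated correlation) and a median of 0.039. The fasting list did not pass without ethanol replicate 1 or 5-Ph-IAA replicate 3 (0.0945 and 0.0509), the DAF-16 list without ethanol replicate 1 or 4 or 5-Ph-IAA replicate 2 (0.0585 to 0.0968), and glycolysis without ethanol replicate 2 or 5-Ph-IAA replicate 2 (0.175 and 0.0968). In the first 2 of these lists, icl-1, the glyoxylate cycle enzyme, was higher with the block (1.27-fold, log2 0.35, SE 0.055, edgeR adjusted p = 0.000616) at 226.3 ± 21.1 CPM with ethanol and 288.4 ± 35.1 CPM with 5-Ph-IAA. Without the block icl-1 passed with DESeq2 (0.0181) and with no filter (4.75e-07). With blocked DESeq2 neither icl-1 (0.203) nor lea-1 (0.318) passed. Among the DAF-16 targets lea-1 was higher with the block (1.15-fold, edgeR adjusted p = 0.0166; not without replicate 2, 3 or 4, at 0.103 to 0.259) and hsp-16.1, also on that list, lower, whereas sod-3, encoding a mitochondrial superoxide dismutase, stood at 1.42-fold and nnt-1 at 1.36-fold without passing (0.485 and 0.365 with the block). The fasting-response gene acs-2 was at 1.252-fold, and acdh-1 and ech-6 were at 0.905-fold and 0.920-fold, none of them past the threshold (edgeR adjusted p = 0.999 for each). For glycolysis gsy-1, gpd-1, tps-2 and gpd-2 lay between 1.09-fold and 1.11-fold and did not pass.

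By camera, the lists closest to TORC1 itself showed small differences or none that passed. The list of TORC1 and TORC2 components (20 tested members) did not pass by camera (adjusted p = 0.653), and no member passed in edgeR, DESeq2 or limma-voom, with 0 members at an unadjusted p under 0.05 in edgeR. Its members with the smallest unadjusted p were lmtr-5 (log2 fold change -0.14, SE 0.073) and sgk-1 (0.20, SE 0.116), followed by raga-1 (-0.08, SE 0.059) and lmtr-2 (-0.082, SE 0.095). Cytosolic ribosomal proteins (78 tested members) were lower as a list (camera adjusted p = 0.00979, and adjusted p = 0.825 with an estimated correlation), with a median log2 fold change of -0.026 and 59 members below 0. The mean of the list was lower in 2 of 4 numbered pairs and higher in 2 (mean difference -0.035, SD 0.101 over the pairs). The pairs therefore show no shared direction. The ribosomal call ended without ethanol replicate 1 or 5-Ph-IAA replicate 1 (0.714 and 0.612). No ribosomal protein gene passed in edgeR, DESeq2 or limma-voom (2 at an unadjusted p under 0.05 in edgeR), and rps-16, rpl-22, rla-1 and rpl-37 lay between 0.874-fold and 0.935-fold. Ribosome biogenesis genes were higher as a list (29 tested members, camera adjusted p = 0.0433, and 0.825 with an estimated correlation, median log2 fold change 0.049), with nol-6 at 1.11-fold, pro-1 at 1.09-fold, tag-151 at 1.06-fold and nol-16 at 0.908-fold, none past the threshold. This call ended without ethanol replicate 1, 2 or 3 or 5-Ph-IAA replicate 3 or 4 (0.0554 to 0.339). Autophagy genes (28 tested members, camera adjusted p = 0.312) and lysosomal lipases and hydrolases (30 tested members, 0.242) did not pass by camera. Fry mixed passed the lysosomal list with the block (adjusted p = 0.00239) and not without it (0.877). It did not pass autophagy with the block (0.0848) or without it (0.938). Adjusted over the list alone, 1 lysosomal gene was higher and 2 were lower with the block. For autophagy, atg-16.1 stood at 1.23-fold, lgg-1 at 0.948-fold, epg-2 at 0.897-fold and atg-10 at 0.814-fold, and among the lysosomal genes nuc-1, asah-1 and asm-3 lay between 0.801-fold and 0.867-fold, with no call in either fit. The cathepsin B gene cpr-1 was higher with the block alone (1.34-fold, edgeR adjusted p = 0.0396), a call that ended with DESeq2 (0.714), with the stricter filter (0.0680) and without replicate 1, 2 or 4 (0.153 to 0.389). The vacuolar ATPase, the proton pump of lysosomes and of the intestinal surface, was lower as a list (20 tested members, 17 below 0, camera adjusted p = 0.0442, and adjusted p = 0.825 with an estimated correlation), except with no filter (0.0674) and without ethanol replicate 2, 3 or 4 or 5-Ph-IAA replicate 1 or 2 (0.0562 to 0.402). Its intestinal subunit gene vha-6 fell with the block (0.878-fold, edgeR adjusted p = 0.0236), though not with DESeq2 (0.281) or without replicate 1, 3 or 4 (0.0633, 0.128 and 0.327), while vha-1, vha-17 and vha-14 stood between 0.920-fold and 0.944-fold without passing.

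Neuronal transcripts, a small part of whole-worm RNA, gave mixed results. Genes of FMRFamide-like neuropeptides were lower as a list (30 tested members, 24 below 0, median log2 fold change -0.14, camera adjusted p = 0.00854), and lost the call with an estimated correlation (adjusted p = 0.724) and without ethanol replicate 2 or 3 (0.0686 and 0.0527). No flp gene passed in edgeR, DESeq2 or limma-voom, with 4 at an unadjusted p under 0.05 in edgeR. The named ones with the lowest fold were flp-26 at 0.595-fold and flp-13 at 0.692-fold, and flp-6 and flp-28 stood at 0.803-fold and 0.848-fold (edgeR adjusted p between 0.927 and 0.999). Pan-neuronal genes (37 tested members) did not pass (camera adjusted p = 0.681, median log2 fold change -0.002), with rab-3 at 0.751-fold, cpx-1 at 0.775-fold, ric-4 at 0.839-fold and sbt-1 at 0.920-fold, none of them past the threshold. The list for touch receptor neurons did not pass either (13 tested members, camera adjusted p = 0.0559).

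**Figure D3:**
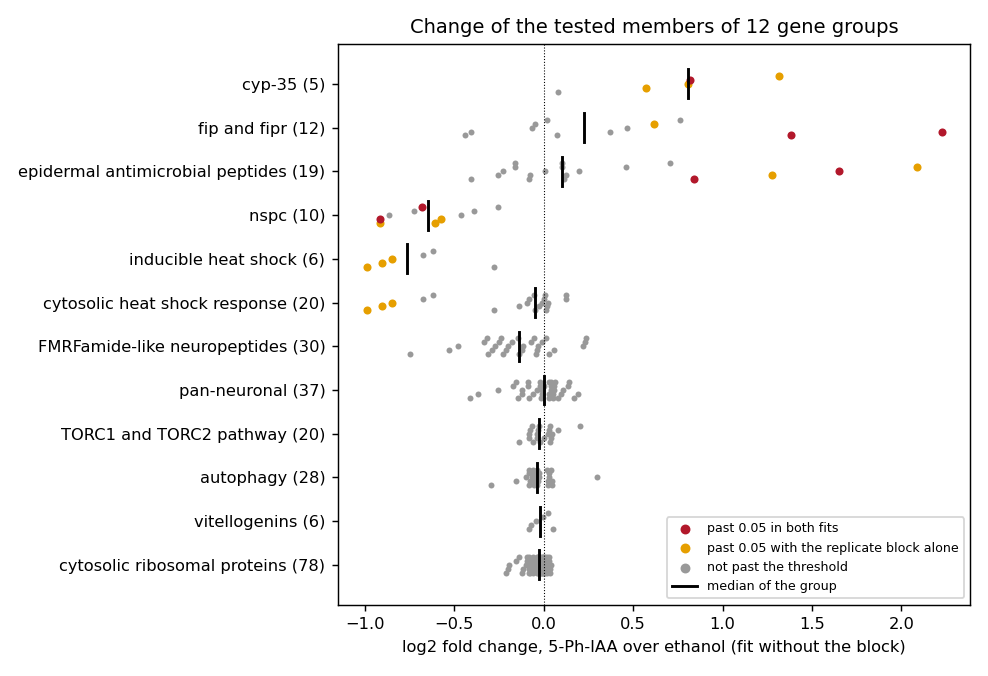
Log2 fold change of the tested members of gene groups (horizontal axis, fit without the block), 1 point per gene and 1 line of points per group, with the number of members in parentheses, a black bar at the median, red points past 0.05 in both fits and orange points past it with the replicate block alone. The medians run from 0.81 for the 5 cyp-35 genes to -0.76 for 6 inducible heat shock genes, both groups named after their values were seen, while that of the fixed list of 20 heat shock genes is -0.051.

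Yolk and cuticle genes, which are abundant in young adults, did not pass as lists. Vitellogenins (6 tested members, camera adjusted p = 0.875) showed log2 fold changes of -0.044 (SE 0.063) for vit-5, -0.07 (SE 0.102) for vit-4, 0.05 (SE 0.074) for vit-2 and -0.081 (SE 0.127) for vit-3. Without ethanol replicate 2, which held the lowest vit-5 and vit-4 levels, the vitellogenin list passed (0.00288). Cuticle collagens (67 tested members, camera adjusted p = 0.153) had a median log2 fold change of -0.045 and a mean difference of 0.006, on either side of 0, with col-95, col-184 and col-101 at 0.861-fold, 0.9003-fold and 0.898-fold and dpy-9 at 1.82-fold, none past the threshold in either fit (col-95 did pass with no filter, 0.0125). The collagen list passed with the stricter filter (0.00991) and without ethanol replicate 2 or 5-Ph-IAA replicate 3 (0.0198 and 0.00228). The mitochondrially encoded genes (11 tested members, 10 below 0) passed with the block (camera adjusted p = 0.0342, and adjusted p = 0.845 with an estimated correlation), against 0.0738 without it. With the stricter filter (0.0277) and without ethanol replicate 1 or 4 or 5-Ph-IAA replicate 1 they passed unblocked (0.0369, 0.00668 and 5.66e-05). In the class scan skr, which codes for Skp1-related subunits of ubiquitin ligases, was lower (19 tested members, camera adjusted p = 0.0319, and 0.920 with an estimated correlation), with skr-8 at 0.718-fold and skr-12 at 0.665-fold, neither past the threshold. Classes col, hsp and cyp passed with the block alone (camera adjusted p = 0.0244, 0.0436 and 0.0438, and 0.959 for each with an estimated correlation).

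Altogether 10 of the 56 lists passed by camera with the preset correlation, 7 higher and 3 lower, and 12 with the block. With an estimated correlation none passed (lowest adjusted p 0.629, with 1 list at an unadjusted p under 0.05), and by fry none passed in one direction (lowest 0.241, with 3 at an unadjusted p under 0.05), while fry mixed passed 0 without the block and 11 with it. Of these 11, the lists of cytosolic heat shock, cytochrome P450 enzymes, UDP-glucuronosyltransferases, the fasting response and raised DAF-16 targets also passed by camera with the block. The rest, which did not, were lysosomal lipases and hydrolases, molting, SKN-1 targets, sperm genes, glutathione S-transferases and one-carbon metabolism. Among the 10 lists past by camera without the block, the means of UDP-glucuronosyltransferases, the fasting response and ribosome biogenesis were higher in 4 of 4 numbered pairs. That of the vacuolar ATPase was lower in 4 of 4. The cytosolic ribosomal proteins were split 2 and 2, and the remaining lists moved in their called direction in 3 of 4. This agreement was not tested. The 12 called genes became 29 with DESeq2, 62 without a filter and 5 with the stricter one, and with 1 library left out their number ran from 6 (without 5-Ph-IAA replicate 4) to 19 (without 5-Ph-IAA replicate 3). Overlapping genes on opposite strands cannot be told apart without a known strand setting, so daf-15 (107 bp shared with col-121), ugt-22 (309 bp), vit-3 (171 bp), vit-4 (150 bp) and cyp-35B1 (102 bp) are uncertain to that extent.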

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

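The tests of epidermal and intestinal RNA, of depth, of shared reads between paralogs and of the compound were chosen only after the results they bear on had been seen, and col-19 and asp-1 were likewise named after their values were seen. Bootstrap intervals come from resampling the genes of a set with the libraries held fixed. They measure the spread between genes, taken as independent, and not the spread between libraries.

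Each file held 1.0069 to 1.0117 reads outside genes for every read inside. A candidate explanation is that reads of a library without strand information were counted by strand, so that those on the other strand fell outside genes. In 15 genes lying inside exons of a gene on the opposite strand, the median read density was 1.51 times that of the host gene (interquartile range 0.288 to 2.226), near what this explanation needs. Only 26.7% of the pairs lay between 0.5 and 2, so single pairs scatter widely. Ratios ran from 0, for C53C9.6 and M79.9 inside hosts with 1575 and 1572 counts, to 3.271 for K11D9.5. Genes without a read go against the explanation, so the pairs do not settle it. No biological explanation was tested for it, and the strand setting itself is not given in the sources used here.

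The peptide genes nlp-34, nlp-29, fip-5 and fipr-23 and cyp-35C1 were higher with 5-Ph-IAA, as were cyp-35A2, cyp-35A3 and cyp-35A5 with the block. A larger share of epidermal or intestinal RNA is argued against by the hypodermis markers (median log2 fold change 0.014, 95% bootstrap interval -0.043 to 0.112, col-19 at 1782 CPM with ethanol and 1642 CPM with 5-Ph-IAA) and the intestine markers (-0.018, -0.055 to 0.051, asp-1 at 1306 and 1231 CPM). A shift shared by genes of their length is argued against, for the 4 peptide genes and not for cyp-35, by 671 genes of like length and level (median -0.035, -0.051 to -0.015). The called, peptide and nspc genes were left out of this set. Its median does not show whether short genes vary more between libraries. Depth is argued against by mean gene counts that differed by -0.71% between 5-Ph-IAA and ethanol (SD 17.9% with ethanol and 11.3% with 5-Ph-IAA). Reads shared between paralogs are not settled by the 4 cyp-35 genes with a log2 fold change above 0.3, since the family was picked because its members rose. Reads with more than 1 alignment are left out of the counts by HTSeq's default. Reads placed at the wrong copy were not tested and stay open. Loss of neuronal DAF-15 and a response of the worms to the compound itself cannot be told apart, since 0 libraries came from worms without the degron given 5-Ph-IAA, and either may underlie the rise.

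All 10 tested nspc genes had a log2 fold change below 0, of which 2 passed without the block and 5 with it, and the class did not pass with an estimated correlation (adjusted p = 0.564). A shift shared by genes of their length is argued against by 156 genes of like length and level, whose median log2 fold change was -0.057 (95% bootstrap interval -0.099 to -0.016). The called, peptide and nspc genes were left out of this set too. A single library is argued against by the median of the class, which was at most -0.535 whichever library was left out. Loss of neuronal DAF-15 and the compound remain open and untested, and the genes of a family with a shared level may vary together between libraries for reasons no label records.

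Chance could not be excluded for the number of called genes. Of the 35 splits of the 8 libraries into groups of 4, 3 gave at least the real 12, and the highest other split gave 34. The other splits that reached 12 keep every numbered pair whole, so they carry the replicate structure and this share cannot decide about chance. Chance could also not be excluded for the genes higher (3 of 35, real 10, highest other 29), the gene lists (13 of 35, real 10, highest other 15) and the gene classes (21 of 35, real 4, highest other 18). Over the 35 splits, the real one included, a median of 8 lists passed (2 to 15). The split with 34 genes set replicates 1 and 2 against 3 and 4, which keeps every numbered pair whole and points to a structure of the samples by replicate number. The other 2 splits of this kind gave 12 genes (1 and 4 against 2 and 3) and 2 genes (1 and 3 against 2 and 4). Among the 8 splits that part every pair the real one alone gave any gene without the block. With the block 1 of these 8, the real one, gave as many as 88 genes (highest other 3), and 2 of 8 gave as many as 12 lists (highest other 12), but 8 splits are too few for a share under 0.05.

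In 10 of 224 groups of 4 libraries 1 library stood far from the other 3, where chance gives 11.2. In ethanol replicate 1 these were ugt-16 at 7.85 CPM (others 4.37 to 4.82), atg-10 at 5.79 CPM (3.45 to 3.64) and the percentage of reads overlapping several genes at 0.299 (0.340 to 0.344). In ethanol replicate 2 they were cpx-1 at 10.5 CPM (7.28 to 7.71), vit-5 at 19684 CPM (23837 to 24160) and vit-4 at 3391 CPM (4630 to 4846), and in ethanol replicate 3 epg-2 at 22.1 CPM (18.6 to 19.1). With 5-Ph-IAA they were col-95 at 577 CPM in replicate 1 (675 to 689), rpl-37 at 27.6 CPM in replicate 2 (21.5 to 22.5) and octr-1 at 1.1 CPM in replicate 4 (1.82 to 1.91).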

How the results depend on the processing

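Tests with thinned libraries, of gene classes under other settings and of the blocked counts and genes under other settings were chosen after the data were seen. The 12 genes (10 higher, 2 lower) became 62 (47 and 15) with no filter, 5 (5 and 0) with the stricter filter, 29 (23 and 6) with DESeq2, 88 (57 and 31) with the replicate block and 6 at an adjusted p under 0.01. The genes lower were 1 with upper quartile factors, 0 with limma-voom and 1 after thinning. With 1 library left out there were 6 to 19 genes, 6 to 17 higher (6 without 5-Ph-IAA replicate 4, 17 without ethanol replicate 3) and 0 to 4 lower. All 12 were among those called with no filter, DESeq2 and the block. The 88 genes with the block were 12 without it, 24 with DESeq2, 57 with the stricter filter and 51 to 92 without 1 numbered pair (51 without replicate 2). Of the genes named by the rule and the lists, the block changed no call other than those printed with it.

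Of the 10 lists, 0 passed with an estimated correlation, 0 by fry in one direction and 0 by fry mixed. Of the 12 lists with the block, 0 passed with an estimated correlation and 0 by fry in one direction, while fry mixed with the block passed 11 of the 56 lists. The 4 classes were 0 with an estimated correlation and by fry in one direction, 7 with the block and 3 to 12 with 1 library left out (12 without 5-Ph-IAA replicate 3), while fry mixed passed 5 of the 114 classes without the block and 14 with it. Over 172 comparisons of called named genes 133 kept direction and call, 39 lost the call and 0 turned. Over 998 of named genes not called, 978 stayed, 16 passed and 4 turned. For genes named with the block 49 of 134 lost the call, for called lists 62 of 150, and for lists not called 13 of 120 passed and 8 turned.

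With 1 library left out daf-15 ran from -0.059 to 0.007 (0.002 without ethanol replicate 1, 0.007 without 5-Ph-IAA replicate 2), vit-2 from -0.030 (without ethanol replicate 2) to 0.11 and vit-3 from -0.187 to 0.011 (without ethanol replicate 4). Adjusted p of the pan-neuronal list ran from 0.366 to 0.977 (higher, 0.920, without 5-Ph-IAA replicate 1), of vitellogenins from 0.00288 to 0.981 (higher without ethanol replicate 1, 3 or 4 or 5-Ph-IAA replicate 1 or 2) and of the cytosolic heat shock response from 0.00771 to 0.985 (higher, 0.977, without ethanol replicate 4). Cuticle collagens turned higher with no filter (0.405). The cause was not tested. Depth limits genes of few counts, such as fipr-23 with 6 to 9 counts per ethanol library.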

Other observations

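The genes of these paragraphs were chosen after their values were seen, by their tests with the replicate block, and each moved the same way in 4 of 4 pairs. For ilys-3, clec-190, octr-1, mec-1 and F57H12.6 this agreement was a condition of the choice, so it adds no support. Among metabolic genes, odc-1, the ornithine decarboxylase of polyamine synthesis, was higher (1.53-fold, edgeR adjusted p = 9.22e-07 with the block and 0.121 without), as was far-3, a fatty acid and retinol binding protein gene (1.54-fold, 1.62e-06 and 0.224). In one-carbon metabolism sams-1, an S-adenosylmethionine synthetase gene, was lower (0.827-fold, 0.000337 and 0.788), as was metr-1, the methionine synthase gene (0.846-fold, 0.00137 and 0.999), while the list of 25 genes did not pass by camera (adjusted p = 0.420). Fry mixed passed the list with the block (adjusted p = 0.0175) and not without it (0.843). With blocked DESeq2 metr-1 did not pass (0.0684).

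Further genes past 0.05 with the block were tep-1, a thioester-containing protein gene, higher (1.31-fold, edgeR adjusted p = 0.00103 with the block and 0.119 without), spp-17, a saposin-like protein gene, higher (1.24-fold, 3.74e-05 and 0.120), ilys-3, an invertebrate lysozyme gene, higher (2.69-fold, 0.0139 and 0.286), and the C-type lectin genes clec-190 and clec-66, lower (log2 fold change -0.63 and -0.37, 0.00164 and 0.0182 with the block), and clec-146, higher (0.43, 0.0183). The list of the intestinal pathogen response (36 tested members) did not pass (camera adjusted p = 0.954, lower by the test and by its median of -0.021, with a mean difference of 0.056). Of neuronal genes, octr-1, an octopamine receptor gene, was lower (0.429-fold, 0.0166 and 0.116), at 3.89 ± 0.727 CPM with ethanol and 1.67 ± 0.381 CPM with 5-Ph-IAA (SD, n = 4), as was mec-1, a gene of touch neuron attachment (0.599-fold, 0.0459 and 0.533). F57H12.6, a gene without a name of its own, went from 9.41 ± 2.88 to 40.4 ± 13.2 CPM (4.28-fold, 0.0302 and 0.167). With blocked DESeq2 tep-1 (0.0759), ilys-3 (0.373), octr-1 (0.394) and mec-1 (0.835) did not pass. Calls also ended without replicate 2 for F57H12.6 (0.384) and ilys-3 (0.0761), without replicate 4 for ilys-3 (0.373), without replicate 3 or 4 for octr-1 (0.172 and 0.135), and with limma-voom, the stricter filter or without replicate 1, 2 or 4 for mec-1 (0.0613 to 0.335). The calls of clec-66 and clec-146 ended with DESeq2 (0.370 and 0.373) and without replicate 2 or 4 (0.0510 to 0.200), and also without replicate 3 for clec-66 (0.0897) and replicate 1 for clec-146 (0.0712).

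Outside neurons, no list of tissue markers passed by camera. The neuronal list of FMRFamide-like neuropeptides did (camera adjusted p = 0.00854, and 0.724 with an estimated correlation). Adjusted p was 0.967 for hypodermis, 0.661 for intestine, 0.743 for body wall muscle, 0.147 for pharynx, 0.332 for glia, 0.147 for germline and meiosis, 0.147 for sperm genes and 0.158 for oocyte and eggshell. For intestine the test and the median (-0.018) were lower and the mean difference was 0.017.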
